A study of Mus musculus with 4 samples.

How the data were processed

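Genomic DNA from 4 samples of mouse liver cells was profiled by array comparative genomic hybridisation, in which a test DNA and a reference DNA carry different dyes and compete for the same probes. Per the labels, all 4 samples have the genotype TAK1LPC-KO_RIP3-_-, so there was 1 group and no second group to compare it with. Per the labels' protocols, DNA was extracted from formalin-fixed, paraffin-embedded (FFPE) sections with a Qiagen kit, and 250 ng was labelled with an Enzo kit. Each sample carried Cy5 and was hybridised against Cy3-labelled DNA pooled from 4 normal livers. The pool is the only control, so each ratio was tested against 0, which leaves out the spread between normal livers. No dye swap was made, and a dye effect of a probe stays in its ratio. Nothing in the labels says that the samples came from separate animals, and p-values therefore measure only the spread between these samples, which may be technical.

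The deposited intensity values are spot signals of Agilent Feature Extraction 10.10.1.1, per the file headers. Per the file headers, the processed intensities were background-subtracted, detrended and dye-normalised with a linear method, with surrogate values for dim spots. The deposited log10 ratio column, which per the file headers holds processed Cy5 over processed Cy3, was used only as a check. On spots without surrogate values it matched the ratios taken here. Probe positions are on mouse build mm9, per the file headers. The array holds 62976 spots, of which 3924 are controls. A deposited table of log2 values for the same arrays was used as an alternative. It correlated with the same array's scanner log2 ratio at 0.91 to 0.92 over 54557 matched probes, with slopes of 1.00 to 1.09, and with any other array's at no more than 0.69. Its columns had medians of -0.04, 0.03, 0.05 and 0.01. Direction and scale of that table were read from this comparison, and its within-array normalisation stays unknown.

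In the main setting the log2 of processed Cy5 over processed Cy3 intensity was taken, control spots and spots with outlier flags were removed, spots of a probe were averaged and each array was centred on the median of its autosomal probes. No loess or quantile step was applied. Of 54669 probes left on all 4 arrays, 54561 were placed on a chromosome, namely 52385 on autosomes, 2172 on X and 4 on Y. The median spacing of autosomal probes was 18.2 kb. Gene names are those of the array's design. A gene's ratio was the mean of its probes, and 20445 autosomal genes were tested, of which 8679 had 1 probe and 4680 had at least 3. Of these names, 14832 are symbols and a further 1578 are synonyms in the RefSeq table of assembly GRCm38, which was used for names only. Exon and intron positions on mm9 were not used here.

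Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment. A gene was called past the threshold at an adjusted p under 0.05 and an absolute mean log2 ratio of at least 0.25. The 19 autosomal medians were tested in the same way without a size limit. Gene lists were tested with fry of limma, which asks whether the members move, on balance, one way. With 4 arrays, the exact sign-flip permutation test cannot give a two-sided p below 0.125. Each array was divided into segments by exact penalised least squares with at least 5 probes a segment and a penalty multiplier of 10, and a segment was called at a mean at least 0.25 from 0. Recurrence was counted in 1-Mb bins, where a bin counted if more than 0.5 of its probes lay in a called segment, against 1000 circular shifts. Where all probes of a gene were not well above background in one channel on every array, the fold was given as a bound. The bound sets the dim channel, per array, at the higher of the probe's own signal and the lowest signal among probes well above background. It is averaged over probes and arrays, and it stays open to dye bias because no dyes were swapped.

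The genes named were fixed by rule before the data were examined, except where the text says that an example was chosen after. The rule takes the 2 targeted genes, then the 10 highest and the 10 lowest autosomal genes past the threshold with at least 3 probes and 1 sign on all 4 arrays, 1 per 1-Mb bin. It also takes up to 4 members past the threshold from each fixed gene list, by absolute mean, and the regions called on all arrays. Of the antigen receptor list no member name occurred in the files, and that list has no result.

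The steps were tested on simulated data. With 200 changed genes among 20445 and the spread of the real genes, limma recovered 8% of genes changed by 0.35, 36% at 0.5, 80% at 1 and 96% at 2 on the log2 scale, and called 0 unchanged genes. The simulation had 110 calls against 7239 in the real data, where the adjusted limit therefore admits a larger unadjusted p. Its rates of recovery and of false calls do not carry over to the real data. Segments put into shuffled array values were recovered in 90% of cases at 500 probes and 0.35, in 100% of cases at 100 probes and 1, and in 10% of cases at 100 probes and 0.58. Segments of 20 probes were recovered in 0% of cases at sizes up to 1. No segment was called on shuffled values without one. Shuffling removes any structure along the chromosomes, so these rates do not carry over to the real arrays either.

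Alternatives set before the data were examined were normexp (offset 50) on spot means and local backgrounds, the deposited log2 table, a filter on probes not well above background, a loess on probe GC content, centring on the mode, slide as a random block, each array left out, and other thresholds. Chosen after seeing the data were a regression on probe GC, GC and probe number within 500 kb (the regional correction), the use of slide means as 2 samples, 4 added tissue lists and the parts of chromosomes 4 and 15. Analyses in Python 3.11.15 used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.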

Results

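Copy number was measured in liver cells of mice labelled as lacking TAK1 in liver parenchymal cells together with RIP3. TAK1, encoded by Map3k7, is a kinase that relays TNF signals to NF-kB and JNK, and RIP3, encoded by Ripk3, is a kinase required for necroptosis. There were 4 arrays with 1 sample each, all set against a pool of 4 normal livers. The labels and the study's title do not state a question beyond sample against pool. Replicates 1 and 2 lay on 1 slide and replicates 3 and 4 on another. Between 84.3% and 89.9% of spots were well above background in the sample channel and between 94.4% and 97.7% in the reference channel. The signal-to-noise ratio was 11.1 to 14.1 for the samples and 18.9 to 24.9 for the pool. The spread of the derivative of the log ratio was 0.38 to 0.42, outside the range accepted by the scanner software on all 4 arrays. The number of arrays limits the precision of all values below.

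Neither targeted gene showed a loss. Map3k7 lay above the pool on the arrays labelled knockout, with a mean log2 ratio of 0.65 ± 0.13 (SD, n = 4; limma, adjusted p = 0.00191). The 4 arrays gave 0.47, 0.68, 0.77 and 0.68. Both of its probes lay above the pool, at 0.89 ± 0.25 for the one at chromosome 4, 32081627 to 32081686, and 0.41 ± 0.12 for the one at 32104945 to 32105004. Ripk3 gave -0.08 ± 0.06 (n = 4; limma, adjusted p = 0.371), with arrays at -0.0019, -0.04, -0.12 and -0.14. Its 2 probes span chromosome 14, 56403814 to 56405496. Whether any of these probes lies in a deleted part is not given in the sources used here, so the ratios do not check the labels. Ripk3 took the other sign, at 0.06, after the regional correction, and passed no threshold there either.

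The clearest focal difference lay in the Skint gene cluster on chromosome 4, a family of immunoglobulin-like membrane proteins known from selection of epidermal T cells. One region was called as a gain on all 4 arrays, from 111745389 to 112202894 (0.458 Mb, 29 probes). Of these probes 26 were not well above background in the reference channel, and the mean of their bounds was 2.857-fold above the pool. Only 23 of the 29 were well above background in the sample channel, so that mean includes probes dim in both channels, where no bound holds. The mean of the measured log2 ratios, 2.96 ± 0.09 (SD, n = 4), rests on dim pool signals and is no estimate of size. The files name Skint4, Skint3 and Skint9 there, besides 2 transcripts without a symbol. No probe of Skint4 or Skint9 was well above background in the reference channel (limma, adjusted p = 5.83e-05 and 8.11e-06). Skint4 was therefore at least 3.99-fold above the pool. The bound of Skint9, 3.405-fold, is a mean over 7 probes, some of them dim in both channels, and is no floor. Skint3, with probe means from -0.06 to 3.87, and Skint6, further along, also passed the threshold (adjusted p = 3.13e-05 and 0.001). Their measured means, 2.40 ± 0.09 and 1.22 ± 0.25, rest in part on dim pool signals, at 6 of 8 probes of Skint3 and 2 of 4 of Skint6, and are no estimates of size. On replicate 3 a second gain was called from 112231972 to 112785680, with a mean of 1.04 over 20 probes, that covered Skint2, Skint10 and Skint6. Only the call was particular to replicate 3. On replicates 1, 2, 3 and 4 Skint6 lay at 1.16, 1.08, 1.58 and 1.06, and Skint2 at 0.29, 0.20, 0.82 and 0.66. The mean of 1.04 also rests in part on dim pool signals and is no estimate of size. Besides those of Skint6, 1 of 6 probes of Skint10 was dim in the pool. So were the probe of ENSMUST00000117091 and the unnamed probes starting at 112273704 and 112362843, all of them dim in the sample channel as well. A filter on probes not well above background removed most of the region, left 0 called segments on any array and placed Skint3 at -0.08.

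**Figure D1:**
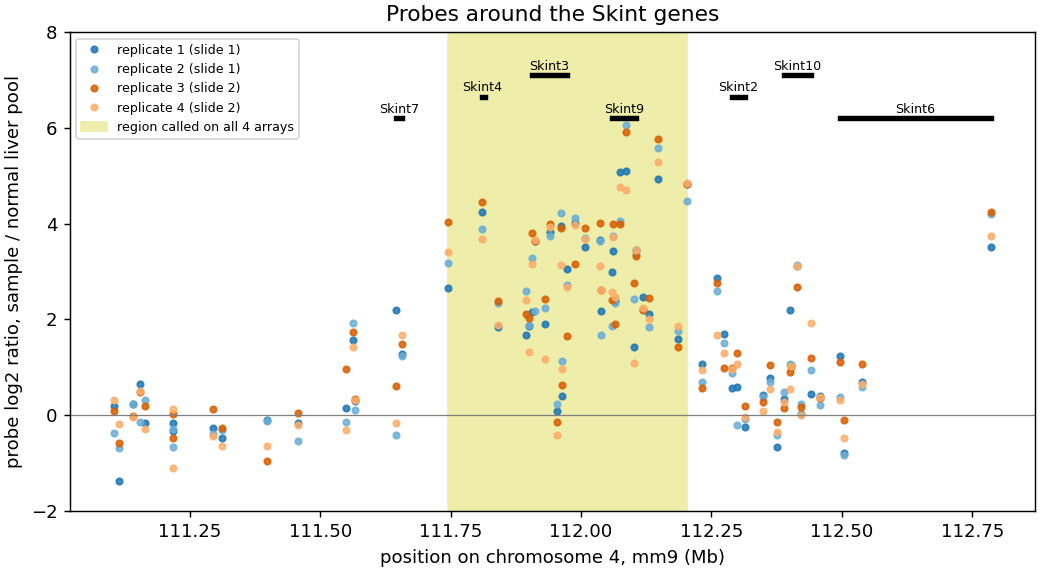
Log2 ratio of each probe (y axis) against its position on chromosome 4 in Mb of mm9 (x axis), with 1 colour per replicate, the region called on all 4 arrays shaded, and bars for the span of each Skint gene's probes. Measured ratios inside the shaded region average 2.96, with the pool not well above background at 26 of 29 probes.

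No other autosomal segment was called, and no loss. Replicates 1, 2, 3 and 4 had 1, 1, 2 and 1 called gains, which held 0.06% to 0.09% of the autosomal probes. The longest was 0.628 Mb. In 1-Mb bins, 1 bin lay in a gain on at least 3 arrays and 0 bins on all 4, counting bins with more than 0.5 of their probes in the gain. None of 1000 circular shifts gave a bin shared by 3 arrays (permutation test, p = 0.000999, the smallest they can give). The shifts treat the arrays as independent, whereas all share 1 pool, so this p does not speak for the samples. At a call size of 0.15 the arrays had 1, 2, 6 and 5 called segments, a mean of 3.5 against 1.25. Replicates 3 and 4, both on slide 2, then held gains over all of chromosome 8, at 0.17 in both, and chromosome 13, at 0.19. They also held a gain of chromosome 4 from its first probe to the Skint cluster, at 0.16 in both. Replicates 1 and 2 had no such calls, although their medians were 0.16 and 0.15 on chromosome 8. On chromosome 13 they were 0.15 and 0.14, and on chromosome 4 up to 110369221 both were 0.13. The calls therefore do not show that the offsets were confined to replicates 3 and 4. A loss of distal chromosome 15 of about 30 Mb was called on replicates 2, 3 and 4, at -0.19, -0.17 and -0.17. Replicate 1 had no such call but a median of -0.16 over that part. The median of that part over 4 arrays, -0.17, was -0.08 after the regional correction, short of the call size. On shuffled values segments of 20 probes were not recovered at any size tested, up to 1, and segments of 100 probes at 0.58 rarely were. On real values 20 probes at 1.04 were called on replicate 3, beside the larger Skint gain. The rates are therefore only a guide, and short or small segments may have been missed.

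Whole chromosomes differed from the pool by small amounts. Chromosome 13 had a median log2 ratio of 0.18 ± 0.04 (SD, n = 4), chromosome 8 of 0.16 ± 0.01, chromosome 14 of 0.11 ± 0.01 and chromosome 4 of 0.09 ± 0.02. The lowest were chromosome 11 at -0.09 ± 0.01, chromosome 1 at -0.08 ± 0.01, chromosome 15 at -0.08 ± 0.01 and chromosome 2 at -0.07 ± 0.003. By limma 16 of the 19 autosomes passed the threshold, 6 higher and 10 lower, with adjusted p of 2.39e-06 for chromosome 13, 6.04e-08 for chromosome 8 and 2.34e-07 for chromosome 14. Each of these 8 had 1 sign on all 4 arrays, and the exact two-sided sign-flip test gave the smallest p that 4 arrays allow. Chromosome 13 was higher on slide 2, at 0.21, than on slide 1, at 0.14, a difference of 0.06 (limma, adjusted p = 3.05e-11, on 2 arrays a slide). With normexp it was 0.04 (adjusted p = 0.0239), and the adjusted p was 0.00096 after the GC correction. The main test used the same standard error, 0.0063, for every autosome, so its p does not measure the spread of chromosome 13 itself. Each slide held different samples, so a difference between slides cannot be told from a difference between samples. Chromosomes 1, 4, 6, 7, 8, 11, 12, 17 and 18 also differed between slides at an adjusted p under 0.05, by no more than 0.04. Chromosome 7, at 0.05, lost its call when arrays were centred on the mode, at 0.02 (adjusted p = 0.137). After the regional correction chromosomes 1 and 18 were lowest, at -0.10 each, with chromosome 11 at -0.06 and chromosome 15 at -0.05. Chromosomes 16 and 17, called in the main test, then lay at 0.002 and 0.004 and lost their calls (limma, adjusted p = 0.729 and 0.620).

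**Figure D2:**
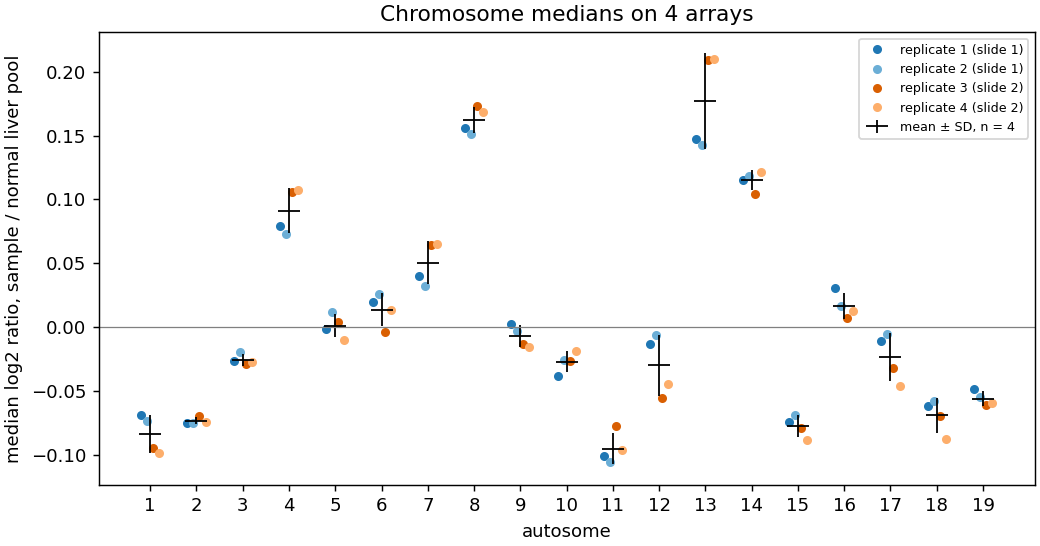
Median log2 ratio of the probes of each autosome (y axis) by chromosome (x axis), 1 coloured point per replicate and the mean ± SD of 4 arrays in black. Chromosomes 13, 8, 14 and 4 stand highest, and on chromosome 13 the points of slide 2 lie at 0.21 against 0.14 for slide 1.

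The X chromosome lay far below the pool, and Y probes well above background in a channel lay above it. The median log2 ratio of 2172 X probes was -0.86 ± 0.02 (SD, n = 4), with arrays at -0.83, -0.85, -0.89 and -0.87. Of 4 Y probes only 1 was well above background in the reference channel on any array, and its log2 ratio was 0.62 ± 0.06. The median of the measured ratios of all 4, 1.72 ± 0.28, is set by dim pool signals. The Y probe at 2442890 to 2442945 was at least 9.54-fold above the pool and the one at 784163 to 784222 at least 1.495-fold. The one at 731532 to 731591 was not well above background in either channel, so it is not shown to differ from the pool. The sex of the animals is not given in the labels. Low X together with high Y is the direction that a difference in sex between samples and pool gives. The X value is therefore not shown to be a copy loss. With normexp the X value was -0.45 and the Y value 0.79, and probes well above background everywhere gave 0.60 for Y. For X and Y alike the exact sign-flip test gave the smallest p that 4 arrays allow.

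Among genes with at least 3 probes, taken 1 per 1-Mb bin, the highest ratios outside the Skint cluster included genes of liver metabolism and plasma proteins. Cyp2e1, a cytochrome P450 that oxidises ethanol, had a mean log2 ratio of 2.38 ± 0.09, C6, a terminal complement component, 1.45 ± 0.25, and Gsta3, a glutathione transferase, 1.19 ± 0.08. Cps1, which starts the urea cycle, had 1.14 ± 0.60, Phkb, a phosphorylase kinase subunit, 1.14 ± 0.13, and Apob, the protein of very-low-density lipoprotein, 1.11 ± 0.10. The transcript ENSMUST00000140320, with 1.06 ± 0.04, and Fmo5, a flavin monooxygenase, with 0.93 ± 0.03, completed the 10 highest together with Skint9 and Skint3. The limma adjusted p of these 10 genes were no higher than 0.00764. The lowest genes were Polr1d, a subunit of RNA polymerases I and III, at -1.76 ± 0.08, Itgb4, the hemidesmosome integrin, at -1.39 ± 0.22, and Cstb, a cathepsin inhibitor, at -1.17 ± 0.16. Sufu, a brake on hedgehog signalling, had -0.99 ± 0.16, Eef1a2, a translation elongation factor, -0.99 ± 0.10, and Gpr107 -0.99 ± 0.27. Slc4a3, an anion exchanger, had -0.94 ± 0.05, Dtna -0.88 ± 0.09, Bai1 -0.81 ± 0.18 and Shank2, a scaffold of synapses, -0.78 ± 0.16. The adjusted p of these 10 genes were no higher than 0.00176.

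Genes with fewer probes reached higher ratios, such as Fabp1, a fatty acid carrier of liver, at 5.36 ± 0.51 on 1 probe, an example chosen after its value was seen. Single probes often decided these means. The 3 probes of Cyp2e1 had means from 0.26 to 3.46, those of Phkb from 0.20 to 2.91, those of Fmo5 from -0.30 to 2.90 and those of Polr1d from -4.76 to -0.05. The probes of Apob ranged from 0.93 to 1.45, those of Cps1 from 0.90 to 1.44 and those of Slc4a3 from -1.07 to -0.76. Cps1 differed between replicates, at 1.72 and 1.58 on slide 1 and 0.56 and 0.69 on slide 2. Among probes well above background everywhere, Phkb had 0.23 and Polr1d -0.07, and neither passed the threshold. The same filter took C6 to 0.78, Itgb4 to -0.62, Sufu to -0.52, Gpr107 to -0.65 and Dtna to -0.56, and the deposited log2 table gave -0.48 for Polr1d and 0.50 for Fmo5. The sizes and ranks of Phkb, C6, Gsta3, Polr1d, Itgb4, Sufu, Gpr107, Dtna and Bai1 are therefore not established. The filter removed at least 1 probe of each, leaving 3 of 4 for Gsta3 and 2 of 4 for Bai1. The size of Fmo5 is not established either, given its value in the deposited table.

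By limma 7239 of 20445 genes passed the threshold, 3302 higher and 3937 lower than the pool, and 10154 had an unadjusted p under 0.05. Of the 7239, 172 were not well above background in at least 1 channel on any array. The test carries the pool and the dye as well as the samples, so a call says that a gene's ratio was steady over 4 arrays and not that its copy number differed. With a size limit of 0.5 the count was 2383, and among the 4680 genes with at least 3 probes it was 1233. The counts of list members given below were not tested against the share over all genes.

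Hepatocyte genes lay above the pool as a group. Of 14 measured members of that list, 9 were higher, 0 lower and 5 not past the threshold, and 9 were higher when adjusted over the list alone. Pck1, which controls gluconeogenesis, had 2.39 ± 0.43, Cyp2e1 2.38 ± 0.09 and Tat, which degrades tyrosine, 2.15 ± 0.07. Pck1 and Tat rest on 1 probe each. The list median was 0.58, and fry gave an adjusted p of 0.000328 upward. Of 18 measured members of the list of strain-polymorphic genes, 8 were higher and 1 was lower, with 9 and 1 when adjusted over the list alone. Of the 8 higher, 5 lie in the Skint cluster, so 1 locus carries most of the count. The members named by the rule were Skint4, Skint9, Skint3 and Skint6, whose order is not established because of dim pool signals. The list median was 0.17 and the fry adjusted p was 0.000328 upward.

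Genes of TNF signalling and cell death moved both ways. Of 26 measured, 4 were higher, 5 lower and 17 not past the threshold, with 4 and 5 when adjusted over the list alone. Over all genes 7239 of 20445 passed, a nearly equal share, so the count is no result about this list. Fadd, the adaptor of death receptors, had 0.79 ± 0.14 on 1 probe, and Zbp1, a nucleic acid sensor upstream of RIP3, -0.67 ± 0.25. Tnfrsf1a, the main TNF receptor, had -0.58 ± 0.07 and Bid, a caspase substrate, -0.50 ± 0.34. The 2 probes of Tnfrsf1a had means of -0.91 and -0.25, those of Bid -0.95 and -0.05 and those of Zbp1 -0.88 and -0.45. The list median was 0.003 and its mean -0.02, and fry gave an adjusted p of 0.733. Without replicate 2 the list had 5 members past the threshold against 9. Zbp1 fell to -0.19 with normexp and lost its call there. Bid lost its call without replicate 1, at -0.47, without replicate 2, at -0.35, and with slide means as 2 samples (limma, adjusted p = 0.0522).

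Oncogenes had 8 higher and 5 lower of 24 measured, with 8 and 5 when adjusted over the list alone, a median of 0.002 and a fry adjusted p of 0.733. Fgf15, the fibroblast growth factor of bile acid signalling, had -0.86 ± 0.31 and Ccnd1, encoding cyclin D1, 0.86 ± 0.37. They sit beside each other on chromosome 7, with probes at 152082668 to 152082715 and 152118344 to 152118403. Mycn had 0.59 ± 0.13 and Igf2 -0.55 ± 0.12. Fgf15, Ccnd1 and Mycn rest on 1 probe each, so their values cannot be told from effects of a single probe. The oncogene count of 13 fell to 8 without replicate 1, to 7 without replicate 3 and to 6 with normexp. With slide means as 2 samples Ctnnb1, Mdm4, Tert, Pik3ca, Stat3, Ccne1 and Sox9 lost their calls (limma, adjusted p from 0.0568 to 0.0864). Of 23 measured tumour suppressors, 6 were higher and 4 lower, with 6 and 4 when adjusted over the list alone. Stk11, which encodes LKB1, had -0.76 ± 0.19, Rb1, the retinoblastoma gene, 0.63 ± 0.41 and Rassf1 0.62 ± 0.13. Stk11 and Rassf1 rest on 1 probe each. Cdkn1a, encoding p21, is among the 4 lower, but its probe was not well above background in the sample channel, its bound was 0.017, and no reduction is established. It lost its call without replicate 1, without replicate 2 and without replicate 3. The tumour suppressor list had a median of -0.07 and a mean of -0.01, whereas fry gave an adjusted p of 0.0359 upward, so median and test differ in sign. With dim members at their bounds the median was 0.02. That p was 0.65 without replicate 4, 0.32 without replicate 2, 0.069 without replicate 1, 0.39 with normexp and 0.93 with mode centring.

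**Figure D3:**
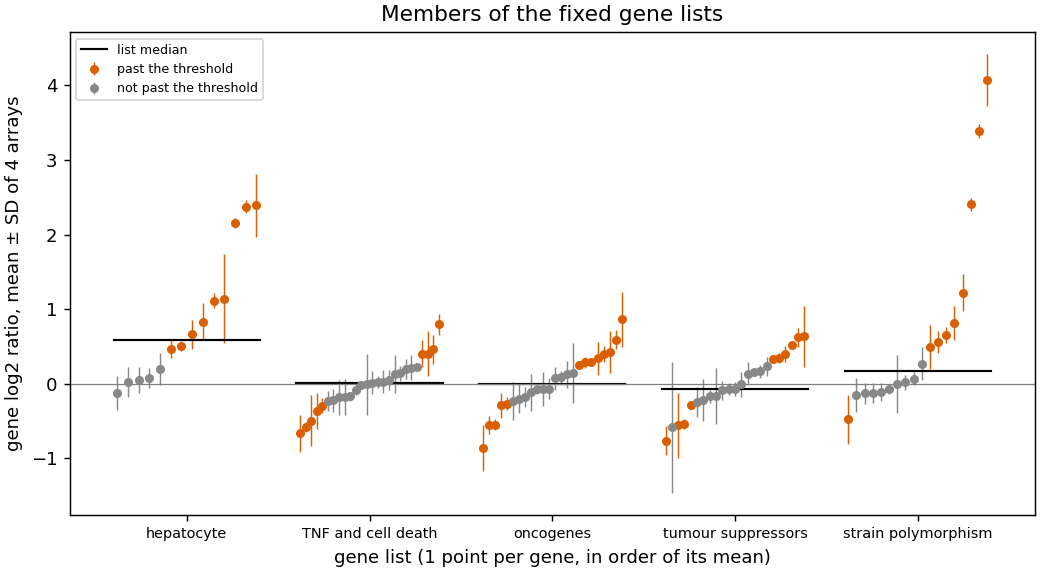
Mean log2 ratio ± SD over 4 arrays (y axis) of each measured member of the 5 gene lists (x axis), members ordered by their mean, in orange where past the threshold and in grey where not, with the list median as a line. The hepatocyte median lies at 0.58 and those of the TNF and oncogene lists near 0.

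The 4 arrays resembled each other, and arrays of the same slide did so most. Across 2238 1-Mb bins, Pearson r was 0.803 for replicates 1 and 2 and 0.801 for replicates 3 and 4, with Spearman rho of 0.782 and 0.786. The 4 pairs on different slides had r between 0.734 and 0.769. Bins are not independent replicates, and a shared pool and dye raise every pair. Differences between the replicates of a slide had a chi-square per bin of 1.13 and 1.15 where probe noise alone gives 1 ± 0.03, which does not tell separate animals from separate hybridisations of the same DNA. By limma 0 genes differed between slides at an adjusted p under 0.05 with a difference of at least 0.25, and 2204 of 20445 did at an unadjusted p under 0.05. Chance gives on average no more than a share of 0.05, which 2204 exceeds. With 2 arrays a slide the test has little power, so the count of 0 does not show that the slides agree. At the adjusted p, normexp gave 4 such genes and the filter on background gave 3.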

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

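The test of single replicates was set before the data were examined, and the look at the unplaced probe was chosen only after. Among 77 sets of 4 array values, 5 had a replicate whose gap to its nearest neighbour, divided by the range of the set, exceeded Dixon's 95% limit, where chance, at 1 in 20 sets, gives about 3.9. Replicate 1 stood apart for Gpr107 (ratio of gap to range 0.851), at -1.39 against -0.80 to -0.89, for Fgf15 (0.918), at -1.33 against -0.68 to -0.73, and for Rassf1 (0.901), at 0.81 against 0.55 to 0.57. Replicate 2 stood apart for Slc4a3 (0.900), at -1.02 against -0.91 to -0.92. Replicate 3 stood apart for the median of chromosome 2 (0.847), at -0.069 against -0.074 to -0.075. The number of such sets is near the chance value.

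One probe on Y sequence that is not placed on the chromosome was outside the comparisons of the report. It was well above background in the sample channel on 4 arrays and in the reference channel on 0, so it lay at least 4.09-fold above the pool. The mean of its measured log2 ratios, 3.60, rests on dim pool signals.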

How the results depend on the processing

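The tests with the regional correction and with slide means were chosen only after the result was seen. Map3k7 stayed above the pool and past the threshold under every alternative run, from 0.41 for its lower probe to 0.71 without replicate 1, with adjusted p from 0.00032 to 0.0118. Ripk3 passed no threshold under any of them and reversed to 0.063 under the regional correction. The cause was not tested. The count of genes was 5477 to 5977 with 1 array left out and 5121 with slide means, and 2383 and 1233 with the stricter limits, which test size or fewer genes by construction. Of the 7239 genes, 65.4% were also called with normexp and 78.8% after the regional correction. The share of higher calls was 45.6% in the main setting and between 38.7% and 49.9% elsewhere. Autosomes past the threshold numbered 13 to 17. The X median was -0.45 with normexp, -0.97 in the deposited log2 table, -0.79 after the background filter, -0.89 after the regional correction and -0.89 with mode centring, and the Y median was 0.79 with normexp and 0.60 after the filter. Called segments per array averaged 2 in the deposited table, 0 after the filter and 3.5 at a call of 0.15, and their share of probes was 0.0692% in the main setting, 0.395% with normexp, 1.45% in the deposited table and 8.29% at 0.15. Bins gained on every array numbered 0 to 1 with 1 array left out. Correlations between slides averaged 0.75, and 0.83 with normexp, 0.80 after the filter, 0.73 after the GC correction, 0.73 after the regional correction and 0.89 in 5-Mb bins, which average more probes. Genes different between slides numbered 4 with normexp and 3 after the filter. The cause was not tested for these, except where a setting acts by construction. The filter removes the probes that are dim in the pool, which also set Skint3 to -0.080. Normexp adds an offset of 50 to both channels, which pulls log ratios toward 0, so the limit of 0.25 is on another scale there. How much of each normexp shift this gives was not tested. Of 36 other named genes, 30 kept direction and call wherever they were measured, and Skint3, Phkb, Polr1d, Zbp1, Bid and Cdkn1a did not. The filter left no probe of Skint4, Skint9 or Cdkn1a. Low signal over background in the samples limits dim genes such as Cdkn1a. No paired analysis was possible because there was only 1 group.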

Other observations

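The tests of GC content, of the regional correction, of the slide difference of chromosome 13, of the dye orientations and of the Skint signals were chosen only after the result was seen, as were the chromosome parts, while the other tests were set before theirs was. Lists added after the first results were seen gave a wider view of the tissue genes. Of 54 measured liver-transcribed genes outside the fixed hepatocyte list, 24 were higher and 3 lower than the pool by limma. Uox, which oxidises urate, had a mean log2 ratio of 2.75 ± 0.25 (SD, n = 4). Apoa2, an apolipoprotein, had 1.73 ± 0.11, while Apoa4 had -0.98 ± 0.18. Uox, Apoa2 and Apoa4 rest on 1 probe each. Of 23 immune cell genes, 0 were higher and 10 lower, among them Mpo at -0.71 ± 0.38 and the T cell receptor component Cd3g at -0.49 ± 0.14. Muscle genes had 3 higher and 8 lower of 29, and neural genes 5 higher and 6 lower of 29. Over all genes 7239 of 20445 passed the threshold, a share near those of the muscle and neural lists. Probes of other names within 100 kb had medians of -0.14 near the immune genes, against -0.18 for the genes, -0.12 near the muscle genes and -0.13 near the neural genes, so the lower values are not shown to be specific to the genes. After the regional correction the immune list had 0 higher and 5 lower, the muscle list 6 and 7, the neural list 3 and 5 and the liver list 27 and 3. These examples were chosen after their values were seen.

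Parts of chromosomes differed too, with limits read from the segments. On chromosome 4 the part from 3159538 to 110369221, which holds Map3k7, had a median of 0.15 ± 0.02 (SD, n = 4), and the part from 114130718 to 155559340 had 0.0008 ± 0.02. On chromosome 15 the part from 73475039 to 103395462 had -0.17 ± 0.01 against 0.02 ± 0.02 for the rest, and the regional correction brought the former to -0.08 ± 0.01.

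The first pattern is the excess of liver-expressed genes. A candidate explanation is that liver transcripts were among the labelled nucleic acid. The added liver list had a median of 0.25, above all of 10000 random lists matched on probe number (percentile 100), while the neural, muscle and immune lists lay at percentiles 23.0, 10.4 and 2.33. A gain or better recovery of whole loci is argued against as the whole cause. The 558 probes of other names within 100 kb of 68 liver genes had a median of -0.0245, against 0.28 for the genes themselves. Such probes had -0.13, -0.12 and -0.14 near the neural, muscle and immune genes and -0.007 near the oncogenes. A part of the excess that covers whole loci therefore stays open. Probe GC content is argued against as well, with a hepatocyte list median of 0.64 after the GC correction and 0.58 before. Partly transcribed loci would widen the range of probes within a gene, and that prediction was not met. The median range was not unusual in the added list (percentile 10.7) or the fixed hepatocyte list (percentile 77.7). Single genes varied, with probes from 0.26 to 3.46 in Cyp2e1 but from 0.93 to 1.45 in Apob. Local DNA recovery at active genes, the make-up of the pool and a dye effect stay open. The percentile of the liver list does not tell transcripts from local recovery or from the pool.

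The second pattern is the offset of chromosomes 8, 13 and 14. Their mean offset was 0.15 before and 0.14 ± 0.02 after the regional correction, which argues against base composition and probe density as the whole cause. Probes without a gene name had 0.17 and named probes 0.15, which argues against transcripts. The pool alone, the same on every array, would give chromosome 13 a slide difference scaled like that of X. The observed excess of 0.0582 did not pass the limit set for it, 3 SD of the differences of the other autosomes (SD 0.0196). Slide, samples and pool therefore cannot be told apart. A copy gain in part of the sample cells is untested, since the design has 1 dye orientation and 1 pool, and a test would need another reference as well as swapped dyes.

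The third pattern is the Skint region. Of its 29 probes, 3 were well above background in the reference channel on any array and 23 in the sample channel. The median reference signal of the region lay at percentile 0.157 of autosomal probes and the sample signal at percentile 23.0, which argues against a gain in the samples over a normal pool. The values are consistent with a segment that is absent or rare in the pool and present in the samples, such as a difference in strain between them. The labels give no strain. Apart from the copy gains of whole loci and of the Skint region and the segment missing from the pool, no biological explanation was tested, because the design has 1 group.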
